A study of Mus musculus with 32 samples.

How the data were processed

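The series holds 32 mouse libraries. Brain, heart, kidney and liver were either flash frozen or fixed in 10% formalin and embedded in paraffin (FFPE). Chromatin from each was immunoprecipitated with an antibody against the C-terminal domain of RNA polymerase II (Pol II), or kept as input. The labels give 2 libraries for each of 16 groups, and replicate numbers 1 and 2 also differ in sequencing date and in library kit. Frozen cores were crosslinked with 1% formaldehyde for 30 min before shearing, whereas FFPE sections were deparaffinized and heated in extraction buffer, so preservation and extraction differ together.

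One table was used, with 27179 genes in 8 columns named by organ and preservation. It is taken to hold the Pol II libraries from its title; no column of input values was used here. The columns carry no replicate number, and whether a column is 1 library or both combined is not given in the sources used here. Each column is called a profile. The n given are profiles, which are not known to be separate animals, so p-values measure the spread between these profiles only. Reads were aligned with Bowtie2 to mm10, counted per gene with featureCounts and processed with limma, per the submitters' processing notes; versions are not given in the sources used here.

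The log2 values deposited by the authors are on the scale that limma's voom function gives: 0.5 reads added to each count, divided by a scaled library total. Taking the lowest value of a column as 0 reads, all values (100%) came out as whole reads within a relative tolerance of 1e-06. The total per profile ranged from 864816 (FFPE liver) to 2178329 (frozen liver), with scaling factors between 0.862 and 1.12. Recomputing voom from these reads and scaled totals returned the deposited values. Both were solved from those values, so this result was fixed beforehand and is no separate check. Because the same 0.5 reads are added at every depth, values of genes with few reads depend on the totals: a gene at 0 reads in both profiles differs between FFPE and frozen by 0.90 in heart, 1.01 in liver, 0.44 in kidney and -0.10 in brain. Of the rows, 1275 had no symbol and were kept under their Entrez number. Entrez numbers of 25275 genes (93.0%) matched the table of gene positions, whose assembly is GRCm38.p6, the build named mm10; all coordinates are on it. Strand of counting is not given, so reads of overlapping genes cannot be separated.

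The design had been fixed for 2 libraries per group, which the table does not give, and the following was adopted after the table was seen. Genes with a log2 value of at least 0 in at least 2 profiles were kept (26758). limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend, Benjamini-Hochberg adjusted p under 0.05) was fitted with organ and preservation as terms. This gave each organ against the mean of the others (2 against 6 profiles) and FFPE against frozen with organ as a block (4 against 4), with 3 residual degrees of freedom and a prior of 19.4. The planned organ contrasts within frozen and within FFPE tissue were fitted as 1 profile against 3 with 2 residual degrees of freedom, where the lone profile is assumed to vary like the others. Differences between organs in the FFPE effect were fitted likewise on the FFPE minus frozen values. FFPE against frozen in a single organ has 1 profile per side and no test; exact binomial intervals (95%) of read ratios cover counting error only. Pol II against input was not analysed here.

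Before the data were examined, 28 gene lists were fixed: cell types of the 4 organs (neurons, very long synaptic and adhesion genes, astrocytes, oligodendrocytes, microglia, cardiomyocytes, proximal tubule, distal nephron and collecting duct, podocytes, hepatocytes), other cell types (erythroid, immune, endothelium, fibroblasts, smooth muscle, skeletal muscle, adipocytes, exocrine pancreas), programmes (immediate early, heat shock, hypoxia and glycolysis, circadian clock, ribosomal proteins, oxidative phosphorylation, housekeeping, nuclear long noncoding RNAs, Y-linked genes), and olfactory and vomeronasal receptors as genes silent in these organs. They were tested with camera at a preset correlation of 0.01, adjusted over 252 tests (9 contrasts). Of these, 66 passed. With an estimated correlation none passed (smallest adjusted p = 0.454), and 17 had an unadjusted p below 0.05. Under the other alternative settings, organ contrasts and FFPE against frozen were adjusted over fewer tests, without the differences between organs in the FFPE effect. Those adjusted p are not on the same footing as the main ones.

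Named genes followed a rule fixed beforehand, adapted to the fit with both preservations: per organ up to 8 own-list members with the largest frozen fold among those past the threshold, up to 6 members not past it, the 8 highest and 3 lowest genes past it whose profiles did not overlap the other organs within either preservation, the 6 highest and 6 lowest for FFPE against frozen with the same sign in 4 organs, the 4 largest differences between organs, and up to 4 members past the threshold of each list called. Predicted genes, genes without symbol, microRNAs, small nucleolar RNAs and olfactory receptors were skipped. Genes chosen after their values were seen are marked as such.

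The code was tested on simulated reads over 26758 genes with 200 changed. For FFPE against frozen and for brain against the other organs, 71.0% of 4-fold changes were recovered, with 3 and 4 false calls, and 0% of 2-fold changes. For frozen liver alone (1 against 3), 0% were recovered at either size. In the data some called genes changed less than 2-fold: of 1995 called in brain, 1604 had a log2 fold of at least 1. The simulated recovery therefore does not carry over to the data. Alternatives were quantile normalization, no filter, a stricter filter (mean log2 of at least 2), array weights, a minimum log2 fold of 1, each profile left out, and camera with an estimated correlation. Chosen after seeing the data were leaving out mitochondrial genes, scaling to silent receptors, voom weights, and thinning to equal total reads, mitochondrial genes included. So were added reads in proportion to depth, leaving out liver, and leaving out FFPE heart and kidney. Leaving out mitochondrial genes also replaced the scaled totals by plain read totals, so its shifts mix both changes.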

Results

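Pol II occupancy over genes was profiled in brain, heart, kidney and liver of mice, each as frozen and as FFPE tissue. Immunoprecipitated DNA over a gene rises with the amount of polymerase on it. The 8 profiles held 1720461 (frozen brain), 1818524 (FFPE brain), 1583260 (frozen heart), 923888 (FFPE heart), 1720986 (frozen kidney), 1458181 (FFPE kidney), 2178329 (frozen liver) and 864816 (FFPE liver) reads in genes. The median gene had between 16 and 39 reads. Mitochondrial genes took 25.6% of reads in FFPE heart and 19.2% in FFPE kidney, against 12% and 7.77% in the frozen profiles of these organs; in brain they took 7.73% in both, and in liver 10.1% frozen and 11.8% FFPE. ND2, a mitochondrial subunit of respiratory complex I, stood at 15.82 in FFPE heart and 13.48 in frozen heart (log2, depth-scaled), whereas COX1, a subunit of complex IV, stood at 14.12 and 13.91. In liver ND2 was at 13.87 in FFPE and 13.32 in frozen tissue and COX1 at 13.19 and 13.66. In brain ND2 was at 12.88 and 12.55 and COX1 at 12.69 and 12.94. Values of mitochondrial genes are given as read levels only and are not taken as Pol II occupancy. Across genes, frozen and FFPE profiles of the same organ correlated with Pearson's r from 0.849 to 0.902, and profiles of different organs from 0.789 to 0.873; genes are not independent replicates.

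The first comparison asked which genes carried more Pol II in one organ than in the others, with each organ's frozen and FFPE profile as its 2 measurements. Errors of these folds are standard errors (SE) from limma, n = 2 against 6 profiles. In brain, all 20 neuronal genes were higher. Snap25, a synaptic vesicle fusion protein, was higher by a log2 fold of 3.07 ± 0.34, Slc17a7, a vesicular glutamate transporter, by 2.67 ± 0.38, and Grin1, an NMDA receptor subunit, by 2.46 ± 0.31. Of the very long synaptic and adhesion genes, 8 of 12 rose, among them Nrxn3 (2.02 ± 0.24); adjusted over the list alone, 12 did. Oligodendrocyte genes rose in 3 of 10 members (4 adjusted over the list alone), with Mobp at 2.30 ± 0.30 and Mbp at 1.95 ± 0.27, both myelin proteins. Astrocyte genes rose in 2 of 10 (5 higher and 1 lower adjusted over the list alone), with Slc1a2, a glutamate transporter, at 1.11 ± 0.22. Astrocyte members not past the threshold included Gja1 (-0.82 ± 0.27). None of the 9 microglia genes passed over all genes (list mean 0.16), with Csf1r at -0.11 ± 0.25 and C1qa at -0.48 ± 0.50.

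The genes with the largest frozen folds in brain included Nptx1 (3.55 ± 0.28, adjusted p = 1.2e-07), a neuronal pentraxin on chromosome 11 from 119538719 to 119547820, and the neurogenic transcription factor Neurod1 (3.15 ± 0.30, chromosome 2, 79452637 to 79456636), Tubb4a (3.12 ± 0.38) and Sncb (2.86 ± 0.52). Ackr1 (3.64 ± 0.54; chromosome 1, 173331886 to 173333503) overlaps the end of the adhesion gene Cadm3 (3.41 ± 0.30; 173331892 to 173368139), so their reads cannot be separated. Grin1os (3.11 ± 0.55) likewise lies inside Grin1. Lower in brain were Depp1 (-3.79 ± 0.37), Clec2d (-3.62 ± 0.38) and Cyp8b1 (-2.82 ± 0.46), a bile acid synthesis enzyme. Among heat shock genes 5 of 10 fell (9 adjusted over the list alone), with Bag3 at -2.26 ± 0.23. Of the immediate early genes 9 of 20 fell and 1 rose (14 and 2 adjusted over the list alone), with Zfp36 at -3.60 ± 0.29. Endothelial genes fell in 2 of 10 (7 adjusted over the list alone), Egfl7 (-2.68 ± 0.25) and Kdr (-1.71 ± 0.23). In all, limma called 918 genes higher and 1077 lower in brain; 870 and 863 of them did not overlap the other organs within either preservation. Scaled to silent receptors, 386 were higher and 776 lower. The balance turned with quantile normalization (1223 and 1182), voom weights (1448 and 1250) and without FFPE heart and kidney (590 and 546). It also turned with mitochondrial genes left out (1070 and 879), a setting that drops the scaling factors too. camera gave adjusted p = 2.1e-28 for neurons, 1.4e-13 for the very long genes, 8.7e-07 for oligodendrocytes, 0.023 for astrocytes, 3.8e-11 for heat shock, 2.6e-06 for immediate early and 5.1e-07 for endothelial genes. In that order these became adjusted p = 0.515, 0.454, 0.690, 0.690, 0.690, 0.690 and 0.515 with an estimated correlation. Without the frozen brain profile 110 genes were higher and 116 lower, and without the FFPE brain profile 261 and 349. Without the FFPE liver profile the counts were 1383 and 1851, and without the FFPE kidney profile 644 and 656. Astrocyte genes were not called without the frozen brain profile (mean 0.33, adjusted p = 0.174).

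In heart, 18 of 20 cardiomyocyte genes rose (19 adjusted over the list alone). Myh6, the main adult cardiac myosin heavy chain (chromosome 14, 54941921 to 54968017), was higher by 5.94 ± 0.28 (adjusted p = 4.7e-12). Cardiac actin Actc1 followed with 5.80 ± 0.39, the troponin Tnnt2 with 4.00 ± 0.31 and the ventricular light chain Myl2 with 4.11 ± 0.52. The atrial genes Nppa (1.78 ± 0.59) and Myl7 (1.44 ± 0.73) did not pass: they stood at 3.38 and 2.12 in frozen heart and at 6.47 and 5.06 in FFPE heart. Beyond the list, Myh7 (4.91 ± 0.28), the slow myosin heavy chain, and Nppb (4.15 ± 0.50), a natriuretic peptide, were higher. Cmtm5 (5.06 ± 0.41) overlaps Myh6 and Mhrt (4.54 ± 0.96) overlaps Myh7, so these values are uncertain. Endothelial genes rose in 5 of 10 members (8 adjusted over the list alone), Kdr by 1.93 ± 0.23 and Egfl7 by 1.82 ± 0.25. Immediate early genes rose in 8 of 20 (16 adjusted over the list alone), with Klf2 at 2.19 ± 0.28 and Klf4 at 2.06 ± 0.25, and heat shock genes in 6 of 10 (6 adjusted over the list alone), with Hspb1 at 3.47 ± 0.35. Oxidative phosphorylation genes rose in 2 of 16 (4 adjusted over the list alone), Cycs and Atp5a1. The fibroblast list had 1 of 7 higher (5 adjusted over the list alone), Col3a1 at 1.13 ± 0.25. Lower were Vmn1r8, Vmn1r83 and Aadacl4fm1, each with 0 reads in both heart profiles.

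limma called 819 genes higher and 582 lower in heart; 762 and 429 of them did not overlap the other organs within either preservation. Scaled to silent receptors, 711 were higher and 231 lower. camera gave adjusted p = 8.3e-47 for cardiomyocytes, 4.2e-10 for endothelium, 4.3e-13 for immediate early genes, 2.1e-07 for heat shock, 2.2e-05 for oxidative phosphorylation and 0.00091 for fibroblasts. In that order these became adjusted p = 0.454, 0.454, 0.575, 0.690, 0.690 and 0.612 with an estimated correlation. Without the frozen heart profile 100 genes were higher and 132 lower, without the FFPE heart profile 253 and 184, and without the frozen or FFPE liver profile 1328 and 955, or 1212 and 975. The lower count was also reduced without the brain profiles (342 frozen, 265 FFPE) and the kidney profiles (324 frozen, 339 FFPE).

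In kidney, 10 of 15 proximal tubule genes rose (15 adjusted over the list alone). Kap, an androgen-regulated kidney protein, was higher by 4.43 ± 0.66, Slc34a1, the sodium phosphate cotransporter (chromosome 13, 55399622 to 55414695), by 3.51 ± 0.28 and Lrp2, the endocytic receptor megalin, by 2.73 ± 0.22. Of the distal nephron and collecting duct genes 7 of 15 rose (12 adjusted over the list alone), among them Pax8 (3.06 ± 0.35), Umod (2.74 ± 0.38) and Slc12a1 (2.42 ± 0.30), the cotransporter of the thick ascending limb. None of the 5 podocyte genes passed (2 adjusted over the list alone), with Nphs1 at 0.17 ± 0.30 and Synpo at 0.05 ± 0.21. Also higher were Ndrg1 (3.37 ± 0.22, adjusted p = 8.2e-09), Cltrn (3.88 ± 0.70), an amino acid transporter partner, and Plau (3.00 ± 0.29). Pfn3 (3.56 ± 0.65) overlaps the end of Slc34a1. The gluconeogenic enzyme Pck1, a member of the hepatocyte list, was higher by 2.41 ± 0.35, while 5 of that list's 24 members were lower. Ppp1r3c (-2.94 ± 0.30), Serpina3m (-2.57 ± 0.52) and Hspb8 (-1.99 ± 0.33) were lower. limma called 246 genes higher and 122 lower, of which 228 and 80 did not overlap. With mitochondrial genes and the scaling factors left out 336 were higher and 101 lower. camera gave adjusted p = 4.6e-34 for proximal tubule, 1.4e-23 for distal nephron and 0.032 for podocytes (adjusted p = 0.454, 0.454 and 0.690 with an estimated correlation). Without the frozen kidney profile 14 genes were higher and 6 lower, without the FFPE kidney profile 37 and 15, and without the frozen or FFPE liver profile 480 and 332, or 441 and 446. The lower count was also reduced without the brain profiles (71 frozen, 54 FFPE) and the heart profiles (68 frozen, 54 FFPE). Podocyte genes were not called without the frozen or the FFPE kidney profile (means 0.57 and 0.48).

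In liver, all 24 hepatocyte genes were higher, also when adjusted over the list alone. The largest were Tat, tyrosine aminotransferase (6.23 ± 0.42), albumin Alb (6.10 ± 0.42, chromosome 5, 90460870 to 90476602) and the fibrinogen chain Fgb (5.89 ± 0.52). Outside the list, Mup3, a major urinary protein (6.38 ± 0.87), Serpina3k (5.76 ± 0.58), Apoa5 (5.69 ± 0.45) and Serpina4-ps1 (4.67 ± 0.81) were higher. Serpina4-ps1 had 1632 reads in frozen and 17 in FFPE liver, so its fold averages unlike values. Mup3 and Serpina3k belong to families of near-identical copies, so the split of reads among them is uncertain. Lower were Srsx, Tas2r137 and Lrfn2, which had 0 reads in frozen liver. Cardiomyocyte genes were lower in 12 of 20 (12 adjusted over the list alone), with Actc1 at -3.27 ± 0.39, and neuronal genes in 7 of 20 (10 adjusted over the list alone), with Eno2 at -1.70 ± 0.31. limma called 1210 genes higher and 907 lower, of which 1069 and 670 did not overlap. Scaled to silent receptors, 773 were higher and 349 lower, and with mitochondrial genes and the scaling factors left out 1057 and 1248. camera gave adjusted p = 1.4e-59 for hepatocytes, 5.2e-12 for cardiomyocytes and 3.9e-07 for neurons (adjusted p = 0.602, 0.655 and 0.690 with an estimated correlation). Without the frozen liver profile 324 genes were higher and 449 lower. The lower count was also reduced without the brain profiles (452 frozen, 516 FFPE), the frozen heart profile (570) and the frozen kidney profile (515).

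The next comparison asked whether frozen and FFPE tissue gave the same organ differences. Hepatocyte genes lay on average 5.40 above the other organs in frozen tissue and 3.08 in FFPE, and all 24 members had the smaller fold in FFPE. Cardiomyocyte genes averaged 3.67 and 3.03, with 16 of 20 smaller in FFPE. For the kidney lists the means were 1.86 and 1.57 and for the brain lists 1.27 and 1.12. A log2 fold of at least 1 in both preservations was found for 23 of 24 liver, 17 of 20 heart, 22 of 35 kidney and 32 of 61 brain list genes. Among the 200 genes with the highest folds in each preservation, 63 were shared in liver, 41 in heart, 38 in brain and 22 in kidney, where independent lists would share 1.49. Shared among the 200 lowest were 3, 9, 11 and 7. Across all tested genes the folds correlated with Pearson's r = 0.379 in brain, 0.267 in liver, 0.258 in heart and 0.135 in kidney; frozen and FFPE contrasts have no profile in common. Among genes with a mean log2 value of at least 2, r was 0.541, 0.399, 0.364 and 0.247 in that order. Among those genes 102 of the 200 highest were shared in liver, 78 in brain, 74 in heart and 65 in kidney, where independent lists would share 1.79, and 10, 35, 9 and 14 of the lowest.

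**Figure D1:**
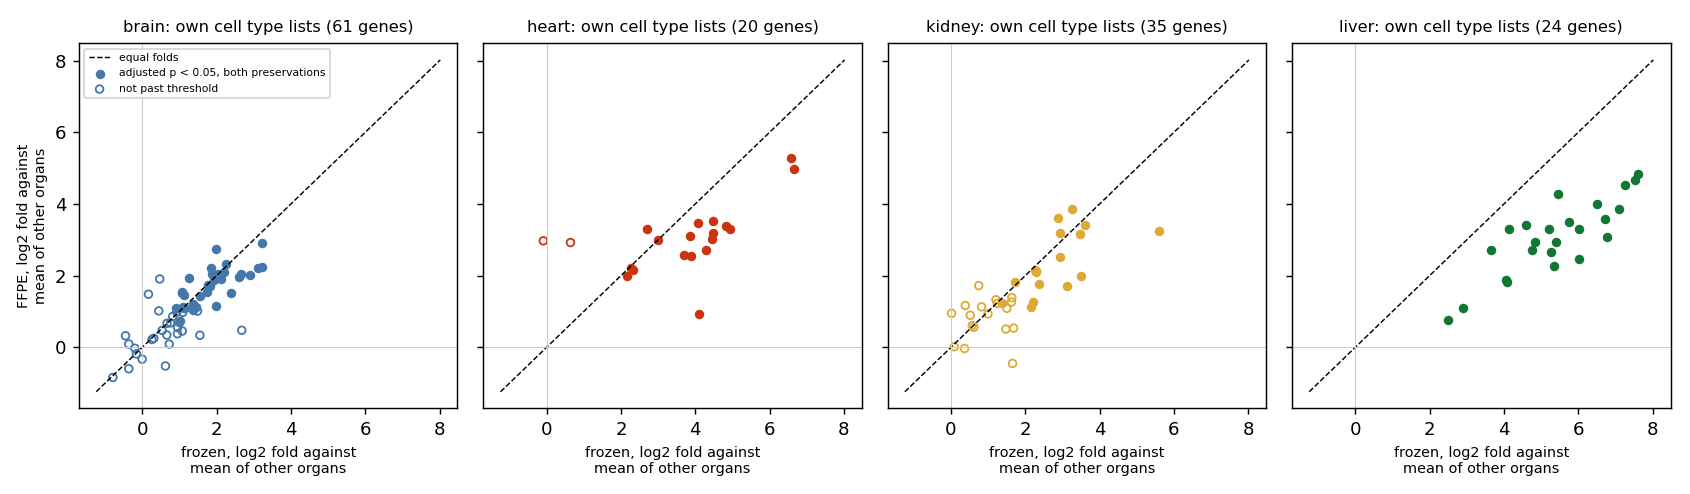
Log2 fold of each organ against the mean of the other organs in frozen (horizontal) and FFPE tissue (vertical), for members of that organ's own lists; filled points passed adjusted p under 0.05 with both preservations together, and the dashed line marks equal folds. All 24 liver genes and 16 of 20 heart genes lie below the line.

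Within a single preservation each organ has 1 profile against 3, so the lone profile has no spread of its own. The folds given above are the effect sizes of these comparisons. Genes past the threshold are not counted for them.

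FFPE and frozen tissue were then compared over the 4 organs. Heat shock genes fell in FFPE: 9 of 10 passed over all genes and 10 when adjusted over the list alone, with a list mean of -1.56. Hspa1b, an inducible HSP70 gene (chromosome 17, 34956429 to 34959238), fell by 2.13 ± 0.21 on the log2 scale (SE, n = 4 against 4 profiles, adjusted p = 1.2e-05), and was lower in each organ, by -1.20 in brain, -2.36 in heart, -2.34 in kidney and -2.60 in liver. The mitochondrial co-chaperonin Hspe1 stood at -1.93 ± 0.23, Hspa8 at -1.85 ± 0.29 and Hsph1 at -1.72 ± 0.20. Hspb1 did not pass over all genes (-0.88 ± 0.31) and was 0.70 higher in FFPE liver. Immediate early genes fell in 2 of 20 members (10 adjusted over the list alone), Dusp1 at -1.15 ± 0.20 and Jun at -0.99 ± 0.21. In the hypoxia list Vegfa fell (-1.35 ± 0.21), 1 of 12 members (2 adjusted over the list alone). Ribosomal protein genes had a mean of -0.50 (-0.65 to -0.33 with 1 profile left out) with 0 of 22 past the threshold (2 adjusted over the list alone), housekeeping genes -0.39 with 0 of 12 (3 adjusted over the list alone) and hepatocyte genes -0.55 with 0 of 24 (2 adjusted over the list alone). The spliceosomal RNA genes Rnu1a1 (-2.38 ± 0.31) and Rnu2-10 (-2.04 ± 0.30), Glrx5 (-3.04 ± 0.64) and Mrgpra3 (-2.65 ± 0.59) were also lower. Mrgpra3 ranged from -0.73 in liver to -5.64 in heart, where the FFPE profile had 0 reads.

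**Figure D2:**
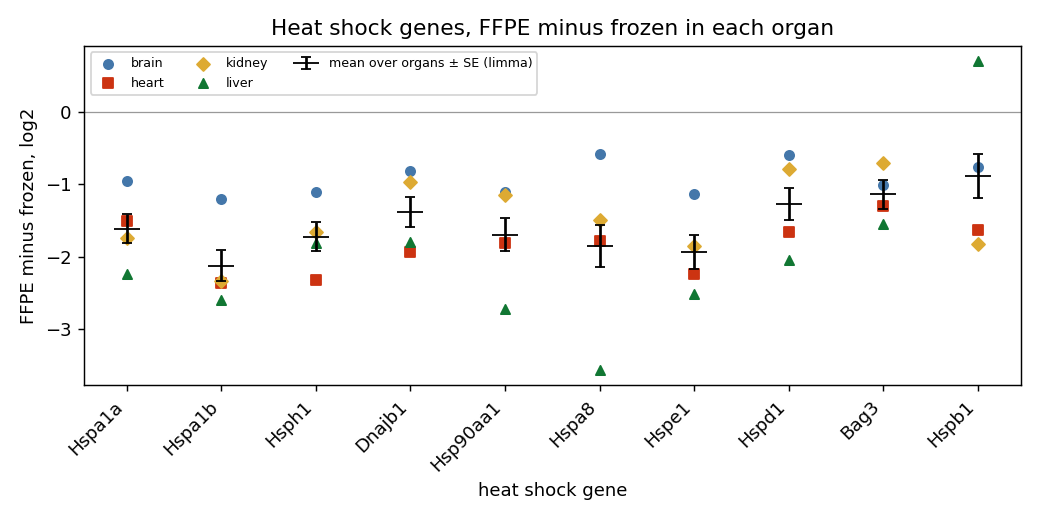
FFPE minus frozen difference (log2) of the 10 heat shock genes in each organ (coloured symbols), with the mean over organs and its SE from limma (black). Apart from Hspb1 in liver (0.70), each symbol lies below 0.

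The genes with the largest folds upward in FFPE had few reads in frozen tissue. BC018473 had 103 reads over the FFPE profiles and 8 over the frozen profiles, Nlrp1c-ps had 98 and 15, and the vomeronasal receptor genes Vmn1r148 and Vmn1r118 had 75 and 12, and 25 and 2 (adjusted p = 0.0013, 0.0062, 0.0065 and 0.038). Vmn1r260 and Vmn1r152 passed too, at adjusted p = 0.010 and 0.019. Of the genes called higher, 11 were Vmn1r genes, for which reads shared between similar copies stay open. limma called 41 genes higher and 113 lower in FFPE. With added reads in proportion to depth the counts were 23 and 77, and Vmn1r118, Mrgpra3 and Jun were not called. camera gave adjusted p = 3.5e-33 for heat shock, 6.8e-07 for immediate early, 6.6e-08 for ribosomal protein, 1.3e-05 for hepatocyte, 0.0024 for housekeeping and 0.0068 for hypoxia genes. In that order these became adjusted p = 0.454, 0.690, 0.763, 0.905, 0.775 and 0.690 with an estimated correlation. Without the frozen heart profile 11 genes were higher and 13 lower, and without the FFPE heart profile 9 and 14. The counts were 23 and 53 without frozen brain, 21 and 59 without FFPE brain, 20 and 75 without frozen kidney, 14 and 69 without FFPE kidney, and 23 and 80 without FFPE liver. With organ in the fit, leaving out either profile of an organ takes that organ out of this contrast. Both settings of an organ therefore give the same folds and are not separate checks. The median of all genes was -0.01, moving to 0.11 with mitochondrial genes and the scaling factors left out and to -0.20 when scaled to silent receptors. Without liver the hepatocyte mean was 0.03 and the housekeeping mean -0.21, neither of them called, and without heart the hypoxia mean was -0.24, not called.

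In single organs the difference had no replicate check. In liver, Serpina4-ps1 had 17 FFPE and 1632 frozen reads, a log2 difference of -5.53 (95% interval -6.36 to -4.89), and the nuclear noncoding RNA Neat1 127 and 2828 (-3.46, -3.73 to -3.21). Fgg stood at -3.58 (-3.90 to -3.29). In heart, Nppa had 70 FFPE and 15 frozen reads (3.09, 2.31 to 4.04), and ND2 46013 and 17063 (2.34, 2.31 to 2.36). In kidney, ND2 differed by 2.51 (2.48 to 2.54) and Trim12a had 35 FFPE reads and 0 frozen reads. The ND2 values are differences in reads over a mitochondrial gene and are not taken as Pol II occupancy. In brain, Apol10a had 46 and 5 (2.98, 1.78 to 4.79), and Taar1 had 0 FFPE reads and 23 frozen reads. The standard deviation of the difference over genes was 0.84 in brain, 0.96 in kidney, 1.10 in heart and 1.16 in liver.

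The FFPE effect of 1 organ was then set against that of the other 3. The organ compared has 1 FFPE minus frozen value, so its own spread is not measured. A deviant profile cannot be told from an organ difference, and genes past the threshold are not counted here. In liver, Apoa1, the main HDL protein, had a difference of -3.56, Fgg of -3.68 and Fga of -3.15. The mean of the hepatocyte list was -2.32.

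Housekeeping genes lay above the silent receptor genes by 3.40 in frozen and 3.08 in FFPE brain, 4.51 and 3.98 in heart, 3.12 and 3.55 in kidney, and 4.66 and 3.11 in liver. The silent receptor medians lay between 1.59 (frozen heart) and 2.31 (frozen kidney). They rest on few reads per gene, so small differences in these distances are uncertain. The mean FFPE minus frozen difference of -0.49 over the 4 pairs did not pass a two-sided exact sign-flip permutation test (p = 0.375); 4 pairs cannot go below p = 0.125. Without liver the mean was -0.14 and without kidney -0.80; between the 90th and 10th percentiles of all genes it was -0.06, with heart at 0.18.

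**Figure D3:**
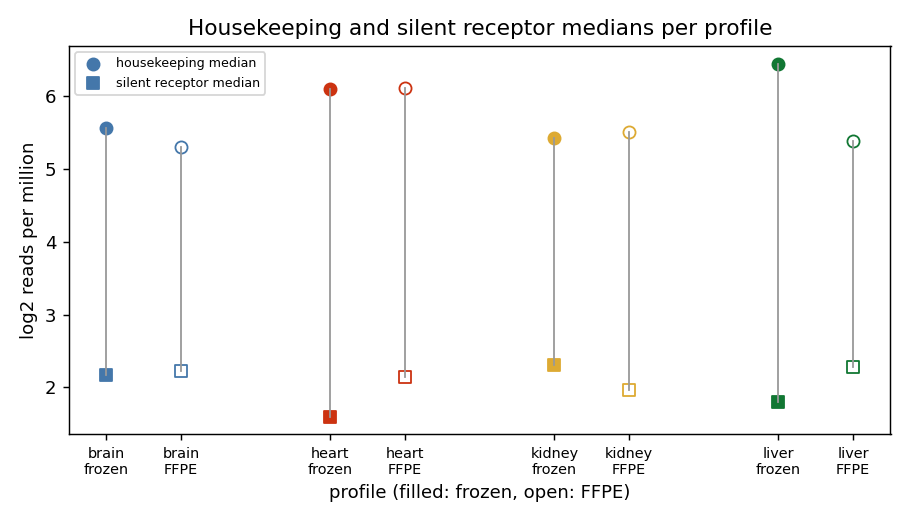
Median log2 value of housekeeping genes (circles) and silent receptor genes (squares) in each profile, filled for frozen and open for FFPE. The distance shrank from 4.66 to 3.11 in liver and was 3.12 and 3.55 in kidney.

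Of the 28 lists, 8 passed camera in none of the 9 contrasts. Their mean FFPE minus frozen differences were 0.16 for adipocytes, -0.07 for microglia, -0.10 for circadian clock, 0.17 for exocrine pancreas, -0.16 for immune cells, -0.24 for nuclear long noncoding RNAs, -0.18 for smooth muscle and -0.19 for Y-linked genes.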

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

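The test of background share below was chosen after the result was seen. The results below were flagged by the test of the FFPE effect in 1 organ against the other 3. The organ compared has 1 FFPE minus frozen value, so its own spread is not measured. A deviant profile therefore cannot be told from an organ difference. In this section, differed means only past the threshold of that fit. No difference between organs is concluded from the number of genes that differed, the called lists or their adjusted p. In liver 142 genes differed. The largest were Lrfn2 (5.40), Cyp2d40 (-4.94), Serpina4-ps1 (-4.84) and Rtl8b (-4.19), the first with 0 reads in frozen liver and the last with 0 in FFPE liver; with added reads in proportion to depth Serpina4-ps1 was not called. By camera at the preset correlation, lists lower in FFPE liver relative to the other organs were hepatocytes (mean difference -2.32), housekeeping (-0.73), ribosomal proteins (-0.67) and immediate early genes (-0.57). Lists higher there were erythroid (1.23), skeletal muscle (1.10), neurons (0.93), cardiomyocytes (0.92) and oligodendrocytes (0.75). With added reads in proportion to depth, where a gene at 0 reads has no difference, the erythroid list was not called in liver (1.05, adjusted p = 0.0754); the other lists of this paragraph were. In brain the heat shock list differed by 0.85. In heart hepatocyte genes differed by 1.20 and cardiomyocyte genes by -0.64. In kidney the values were 0.60 for ribosomal proteins, -1.36 for erythroid genes and -0.62 for silent receptors. Each value also carries changes in the other organs: hepatocyte genes themselves moved by 0.36 in heart and -2.29 in liver, and ribosomal protein genes by -0.05 in kidney and -1.01 in liver. None of these lists passed with an estimated correlation. In each of 14 sets of 4 profiles (7 technical measures in frozen and in FFPE tissue) no profile stood apart from the rest by Dixon's criterion. With 4 values from different organs this criterion flags only an extreme profile, so a deviant profile is not excluded.

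Hepatocyte genes were less above the other organs in FFPE than in frozen liver. Depth argues little: after thinning all profiles to the shallowest total the mean difference was -2.23, or 96.1% of its value. A larger share of background in the FFPE liver profile may contribute, since housekeeping genes also dropped there relative to silent receptors, by a median of -1.43, against -0.83 in heart, -0.22 in brain and 0.53 in kidney. A difference between the livers sampled stays open and was not tested.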

How the results depend on the processing

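The alternatives marked here as chosen after seeing the data are mitochondrial genes left out, scaling to silent receptors, voom weights, thinning, added reads in proportion to depth, without liver, and without FFPE heart and kidney. With mitochondrial genes left out, plain read totals also replaced the scaled totals. No paired analysis was possible because the columns carry no replicate number; frozen and FFPE profiles were paired by organ only. Of the alternatives chosen before the data were seen, the replicate block, input-subtracted values with and without it, only the groups compared, the pseudocount and the count-based alternative were not run, nor were array weights for fits of 1 profile against 3. Of 724 alternative values for 43 results 560 were labelled the same. For counts this label does not mean unchanged. It covers heart higher going from 819 to 1222 with voom weights, and FFPE higher from 41 to 60 with quantile normalization. Of 3613 alternative values for 203 values of named genes 3199 were the same, 406 weaker, 8 stronger and 0 reversed. Where values moved, the cause was not tested. Counts within a single preservation, and for differences in FFPE effect, set 1 value of an organ against the other organs. They show how the fit depends on processing and are not read as organ differences. Counts are given as higher and lower in brain (918, 1077), heart (819, 582), kidney (246, 122), liver (1210, 907) and FFPE against frozen (41, 113). Array weights gave brain 1572 and 1999, kidney lower 226, liver lower 524 and FFPE higher 77. Quantile normalization gave kidney 488 and 201. It lowered the counts for frozen liver and for the liver difference in FFPE effect to a small part of those in the main fit. The stricter filter gave FFPE higher 24, and r of 0.541 in brain, 0.364 in heart, 0.247 in kidney and 0.399 in liver. No filter gave frozen liver 101, and leaving out mitochondrial genes 64. Scaling to silent receptors gave brain higher 386, heart lower 231, kidney 107 and 79, liver 773 and 349, frozen brain 1, frozen heart 5, FFPE heart 7, the heart difference in FFPE effect 8, frozen liver 463 and the liver difference 45. It gave list means of 0.33 for astrocytes and 0.42 for podocytes, neither called (adjusted p = 0.0646 and 0.0695), and reversed microglia from 0.16 to -0.0229, called in neither. Voom weights gave brain higher 1448, heart lower 351, kidney 517 and 189, liver higher 1892, FFPE against frozen 62 and 248, FFPE brain 149, FFPE heart 4, frozen liver 387, FFPE liver 26 and the liver difference 288. Thinning gave FFPE higher 25, FFPE brain 0, frozen liver 76 and the liver difference 60. Added reads in proportion to depth gave FFPE higher 23, FFPE brain 0, FFPE heart 0, frozen liver 18 and FFPE liver 0. Without FFPE heart and kidney the counts were brain 590 and 546, heart 365 and 345, kidney 92 and 48, and FFPE against frozen 15 and 75, with hypoxia (-0.27, adjusted p = 0.102) and podocytes (0.48, adjusted p = 0.12) not called. Without liver, housekeeping was not called (-0.21, adjusted p = 0.235) and hepatocytes in FFPE against frozen reversed (0.033, adjusted p = 0.826). With an estimated correlation no list was called: heat shock -1.56, very long genes 1.33, cardiomyocytes 3.35, proximal tubule 2.18 and distal nephron 1.66 (adjusted p = 0.454), neurons 1.92 (0.515), hepatocytes in liver 4.24 (0.602), immediate early -0.41, hypoxia -0.35, astrocytes 0.51, oligodendrocytes 1.19 and podocytes 0.53 (0.690), ribosomal -0.50 (0.763), housekeeping -0.39 (0.775) and hepatocytes in FFPE against frozen -0.55 (0.905). Leaving out 1 profile at a time, ranges of counts were brain higher 110 to 1383 and lower 116 to 1851, heart 100 to 1328 and 132 to 975, kidney 14 to 480 and 6 to 446, liver 324 to 1642 and 449 to 1227, FFPE against frozen 9 to 34 and 13 to 80. They were frozen brain 0 to 2, frozen liver 0 to 291, FFPE brain 2 to 336, FFPE heart 0 to 253, FFPE kidney 0 to 22, FFPE liver 0 to 154, and for differences in FFPE effect heart 0 to 71, kidney 0 to 2 and liver 107 to 802. Ranges of list means were neurons 1.76 to 2.07, astrocytes 0.33 to 0.69, cardiomyocytes 3.03 to 3.67, podocytes 0.48 to 0.57, hepatocytes in liver 3.08 to 5.40, heat shock -1.77 to -1.41, ribosomal -0.65 to -0.33, immediate early -0.53 to -0.27, housekeeping -0.46 to -0.21, hypoxia -0.42 to -0.24, and hepatocytes in FFPE against frozen -0.85 to 0.033, reversed without either liver profile. The signal range difference lay between -0.80 and -0.14; for the 90th minus 10th percentile it was -0.06.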

Other observations

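The tests on adjacent genes, on gene families, on silent receptors and on profiles without liver were chosen after the results were seen, as were the gene groups of the next paragraph.

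Outside the fixed lists, 12 of 62 replication-dependent histone genes were called lower in FFPE and 50 were not called; no test of the group was made. The median was -1.86 in liver, -0.76 in heart, -0.51 in brain and -0.36 in kidney. Of 10 spliceosomal RNA genes 3 fell, and of 12 U3 small nucleolar RNA genes 4 fell (median -2.46 in liver and -0.31 in kidney). These are short, clustered families of near-identical copies, so single members are uncertain. Mt2, a metallothionein, fell by 1.72 ± 0.27 on the log2 scale (SE, n = 4 against 4 profiles, limma adjusted p = 0.0020). Neat1 fell by 1.59 ± 0.31 (limma adjusted p = 0.012), with -0.23 in brain, -1.32 in heart, -1.34 in kidney and -3.46 in liver. Ddit3, a stress-induced transcription factor, fell by 1.30 ± 0.25 (limma adjusted p = 0.011).

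Chance as the source of the FFPE effect was checked with other splits of the 8 profiles into 4 and 4. Of 32 splits that could be fitted, 1, the real one, gave as many genes (154). With organ in the fit, a split that keeps an organ's profiles together tests only the other organs. Such splits also come in pairs with identical counts, so the 32 are not separate fits. The highest other count, 86, came from frozen against FFPE heart and liver, so it is not a chance value. Only 8 splits part all 4 organ pairs, which is too few for a share under 0.05; the highest other count among them was 0.

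Heat shock genes were lower in FFPE than in frozen tissue. The list median of -1.66 lay below the lowest of 10000 random lists matched on frozen level (-0.93, with a median of -0.13 over the lists). These lists were not matched on gene length or on reads per length, so a smaller signal range stays open. Among 74 chaperone and co-chaperone genes, grouped after the result was seen, 16 were called lower, 47 had a negative sign and the median was -0.18. Liver alone does not account for it, since the list mean was -1.41 without both liver profiles. A response to handling before freezing, or the extraction at high heat, may be behind it; no test here parts these, and no biological explanation was tested.

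Genes higher in FFPE than in frozen tissue in all organs often had a neighbour that was also higher, called or not; of the 41, 23 were called with added reads in proportion to depth. Of 36 with a position, 30 (83.3%) had an adjacent tested gene at least 0.5 higher, against 13.9% to 44.4% in random lists of like level; with added reads in proportion to depth, under which genes at 0 reads do not differ, it was 15 of 19 (78.9% against 5.26% to 42.1%). This may reflect copy number differing between the animals behind the frozen and the FFPE tissue, as a hypothesis; genes lower in FFPE were also more often adjacent (47.2% against 14.2% to 29.2%), so adjacency alone is not specific. Reads shared between near-identical copies stay open, as 61.1% had a gene of the same symbol root nearby. A difference in background DNA reads is undecided: FFPE minus frozen correlated between organs across 1481 silent receptor genes with a median r of 0.12, but these include the Vmn1r genes that prompted the question, and across the other 1252 it was 0.00668.

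At single loci chosen after their values were seen, Ide (1.21 ± 0.19) and Fgfbp3 (1.43 ± 0.23) on chromosome 19 were higher in FFPE. Beside Ide, 4931408D14Rik (0.96 ± 0.26) did not pass but was positive in each organ. Marchf5, which starts at 37207540, lies between Fgfbp3 and Ide and stood at -0.18 ± 0.20. Kif11, on the other side of Ide, stood at -0.16 ± 0.23. On chromosome 17, Glo1 (-1.26 ± 0.23) and the adjacent Dnah8 (-0.86 ± 0.19) were lower. The genes on either side, Btbd9 (-0.29 ± 0.21, but 0.38 in kidney) and Glp1r (-0.65 ± 0.40), did not pass.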
